A study of Rattus norvegicus with 547 samples.

How the data were processed

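Gene expression was measured by hybridizing biotin-labelled RNA to arrays with 31099 probe sets. The cells were cultivated hepatocytes of male Wistar rats. The 547 arrays comprised 34 of cells taken at the start of incubation (T0), 256 of cells kept with solvent (solvent control) and 257 of cells treated with 1 of 29 compounds for 24 h. Each compound was used at 3 concentration levels (high, middle and low), except that the high level of dehydroepiandrosterone was not analysed here, so its middle level counted as its highest. This gave 86 pairs of compound and concentration. The submitters' table placed 9 compounds in the genotoxic class (GT), 11 in the non-genotoxic class (NG) and 9 in the class of non-carcinogens (NC).

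The deposited values were log2 expression levels, 1 per probe set and array, between 2.00 and 14.6. The scale was read from this range, and the submitters' processing notes named RMA (robust multi-array average). Its version, and whether it was run on all arrays together, are not given in the sources used here. Array medians ranged from 5.24 to 5.76 on the log2 scale, so the arrays did not share 1 distribution. The number of arrays limits the precision of every value below. No value of the table was left out, apart from the 57 control probe sets (IDs beginning with AFFX). These were used only for array checks and for the beta-actin, GAPDH and hexokinase values, which left 31042 probe sets for the tests.

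Every group of arrays was planned with 3 replicates. Prazosin at its high level had 2 control and 3 treated arrays, and 3-methylcholanthrene at its high level had 2 of each. Per the design text of the series, the replicates of a compound came from different rats on different days, and treated and control wells shared 6-well dishes. A treated array and the control array with the same replicate number were therefore taken as 1 dish. Whether such pairs deviated together was checked on the data. The mean correlation of deviations was 0.0466 for arrays with the same number and -0.0228 for arrays with different numbers. In 102 of 257 cases the treated array lay closest to the control of its own number, and in 9 of the 84 comparisons with 3 pairs all correlations exceeded 0.1. The pairing was thus weak in the values. The counts per compound and level, their totals, and the shared, class and related compound counts were repeated without it.

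Calculations used R 4.3.3 and limma 3.58.1. For each compound, limma (lmFit and eBayes) was fitted to the differences of treated minus control within dishes, with all concentrations of the compound in 1 fit. Probe sets with a Benjamini-Hochberg adjusted p under 0.05 are called below. T0 arrays were compared by limma with solvent control values averaged to 1 value per compound and replicate number, 87 in all, because nothing ties a T0 array to a rat or a compound. The labels do not say whether control values of different compounds came from different rats. If rats were shared, the 87 values are not all independent, and the p-values of this comparison are too small. Classes were compared by limma on 1 value per compound, its mean dish difference at the highest concentration. Related compounds used at equal concentrations were compared by testing the difference between their effects. Where an SE follows a log2 fold change, it is limma's moderated standard error, and the number of dishes is 3 unless stated.

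The named probe sets followed a rule. For each compound with at least 20 calls, it took the largest rises and falls at the highest concentration among probe sets called and changed in the same direction in every dish. For T0 it took the largest changes each way, for classes and related compounds the largest differences called, and for shared responses the probe sets called in the most compounds. At most 2 rises and 2 falls per comparison are printed. This rule, the comparisons, the threshold and most of the alternatives were fixed before the data were examined. The files used here do not pair probe sets with genes, so every probe set was tested under its own ID. For the same reason 18 pathway lists and 6 lists of cell type markers, also fixed in advance, were not applied.

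The procedure was tested on simulated data with known changes. Of changes of 1 on the log2 scale, 83.6% were recovered with 3 dishes, 88.1% with 3 and 3 unpaired arrays, 70.1% for the difference between 2 compounds, 86.6% between classes and 100% between T0 and control. For changes of 0.5 these shares were 14.9%, 34.3%, 8.96%, 59.7% and 94.0%. Between 5 and 10 unchanged probe sets were called per simulation. The simulated values were independent between arrays and between probe sets, with no dish effect and no array batch. These shares and false calls therefore hold for such data only and do not cover structure shared by real arrays.

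Array checks gave 3 kinds of technical structure, with limits set after the data were seen. A batch of 145 arrays, 11 of them T0 arrays, had medians under 5.4. The mean of the hybridization spike-ins, control RNA added before hybridization, was at most 3.84 on 16 arrays and at least 8.63 on the others. For 4 arrays the median correlation with the other arrays was under 0.91. No pair of arrays was identical, and the highest correlation between arrays was 0.997.

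Alternatives fixed in advance were a fit with no replicate block, 1 fit over all compounds with a shared spread, only probe sets brighter than the median, quantile normalization of the arrays of a compound, eBayes with trend and robust settings, and leaving out each replicate number. For T0 they were every control array as its own replicate, quantile normalization of all arrays, controls of the low concentration dishes, and a fold change of at least 2. For classes they were the middle concentration, the mean over concentrations, effects scaled to equal size, and 3-methylcholanthrene left out. Added after the data were seen were terms for the array batch or the spike-in signal, fits within batches, the 4 distant arrays left out, NNM and MDA left out of the class comparison, 2AAF left out, and its low and middle controls exchanged. The p-values measure only the spread between these samples.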

Results

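The study asked how hepatocytes in culture respond to liver toxicants and carcinogens of different classes. Expression was measured on 547 arrays of cultivated hepatocytes from male Wistar rats. Of these, 34 were taken at the start of incubation, 256 after 24 h with solvent and 257 after 24 h with 1 of 29 compounds at a high, middle or low concentration. There were 3 replicates per group except for 2 control arrays of prazosin at the high level and 2 treated and 2 control arrays of 3-methylcholanthrene at the high level. Array medians lay between 5.24 and 5.76 on the log2 scale. The values are log2 expression levels of 31042 probe sets, and the number of arrays limits their precision.

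The first comparison asked what 24 h of culture with solvent alone did to the cells. Culture changed a large part of the transcriptome by small amounts and a small part by large ones. In total, 13914 probe sets (44.8% of those tested) differed between T0 and solvent control, 7282 higher and 6632 lower after culture. Of these, 544 changed at least 2-fold, and large changes were mostly losses, with 410 lower and 134 higher in the cultured cells. The probe set 1367577_at rose from 9.33 ± 1.04 (SD, n = 34) to 12.69 ± 0.79 (SD, n = 87), a log2 fold change of 3.36 ± 0.17 (SE, adjusted p 1.05e-36), and 1368247_at rose by 2.47 ± 0.16. The probe set 1385397_at went from 10.95 ± 0.69 to 6.69 ± 1.06, a log2 fold change of -4.27 ± 0.19 (adjusted p 1.42e-41), and for 1368627_at it was -3.52 ± 0.18. The p-values of this comparison take the 87 control values as independent, which the labels do not establish.

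These changes were present in both array batches, defined by the array medians. Within the batch of lower medians (11 T0 arrays) limma called 13188 probe sets, and within the other (23 T0 arrays) 17770. With the batch as a term it called 18930. Of the 544 probe sets with 2-fold changes, 541 were called in the same direction in each batch. For 1367577_at the log2 fold change was 3.26 and 3.41 within the batches, for 1368247_at 2.10 and 2.64, for 1385397_at -3.42 and -4.61, and for 1368627_at -3.73 and -3.30. Across probe sets, which are not independent replicates, the changes in the batches correlated with r = 0.770. Of the control genes, beta-actin was higher after culture by 0.31 (two-sided permutation p 1e-05, the smallest possible, adjusted p 3e-05) and GAPDH by 0.33 (p 2e-05, adjusted p 3e-05). Hexokinase changed by -0.07 (p 0.005, adjusted p 0.005). Within the batches the differences were 0.13 and 0.43 for beta-actin, 0.02 and 0.49 for GAPDH and -0.05 and -0.09 for hexokinase, and all kept their direction after quantile normalization.

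The second comparison asked what each compound changed at its highest concentration. Most compounds changed expression, and the size of the response spanned from 0 to 13297 probe sets. In total, 52757 calls were made, 24417 rises and 28340 falls, and 21 of the 29 compounds had at least 20. Large changes, pooled over compounds, were mostly falls. Of 7809 calls with at least a 2-fold change, 6117 fell and 1692 rose, and after quantile normalization 5479 fell and 1939 rose. Of these falls as first called, MDA had 1522 and ibuprofen 1118. Several compounds had more such rises than falls, among them cefuroxime (221 and 99) and C.I. Direct Black (145 and 74). The 6 compounds with the most calls held 70.7% of the total. They were N-nitrosomorpholine (NNM, 13297 calls), methylendianiline (MDA, 6119), ibuprofen (5317), Wy-14643 (5068), methapyrilene (4213) and C.I. Direct Black (3282). With no replicate block the total was 58261. Without replicate 1 it was 28923 and without replicate 2 it was 28812.

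For 6 compounds limma called 0 probe sets at the highest concentration. They were N-nitrosopiperidine, methylcarbamate, acetamide, dehydroepiandrosterone, ethionine and 1,4-dichlorobenzene. Their counts at an unadjusted p under 0.05 were 3555, 1609, 1795, 2363, 2757 and 1460, where chance gives 1552.1. Several of these counts were not stable. N-nitrosopiperidine had 1653 calls without replicate 1, dehydroepiandrosterone 27 without replicate 3 and ethionine 8 without replicate 3. With the spread pooled over all compounds dehydroepiandrosterone had 4883, N-nitrosopiperidine 1590, ethionine 347 and 1,4-dichlorobenzene 129, and ethionine had 9 after quantile normalization. Acetamide had 2 and dehydroepiandrosterone 1 with no replicate block.

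Acetaminophen had 1 call and prazosin 10 (0 without replicate 2). Acetaminophen had 834 calls with no replicate block and 25 without replicate 1 at every level. Its count was 947, on 2 dishes, when only high treated replicate 1 was left out, an array whose median correlation with the other arrays was 0.307.

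Fewer calls were made at the middle level, and at the low level most came from 1 compound. At the middle level there were 7227 calls (2485 rises and 4742 falls), and 16 compounds had at least 20. This total was 1518 without replicate 2 and 10895 without replicate 3. At the low level there were 12978 calls, 6335 without replicate 2 and 5947 without replicate 3, and 8 compounds had at least 20. Of these 8, 6 still had at least 20 with no replicate block, while propranolol went from 406 to 0 and 4-(methylnitrosamino)-1-(3-pyridyl)-1-butanone (NNK) from 72 to 3. Of the low level calls 9861 came from 2-acetylaminofluorene (2AAF), whose 3 control arrays at that level lacked spike-in signal while the treated arrays had it. Without 2AAF the total was 3117. Of the 28 compounds with a high level here, 19 had the most calls at that level, 4 at the middle and 2 at the low level. The probe sets called at the high and middle levels overlapped. Methapyrilene had 1180 in common in the same direction where 129.06 are given by independence, and cyproterone acetate had 610 where 19.2 are.

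**Figure D1:**
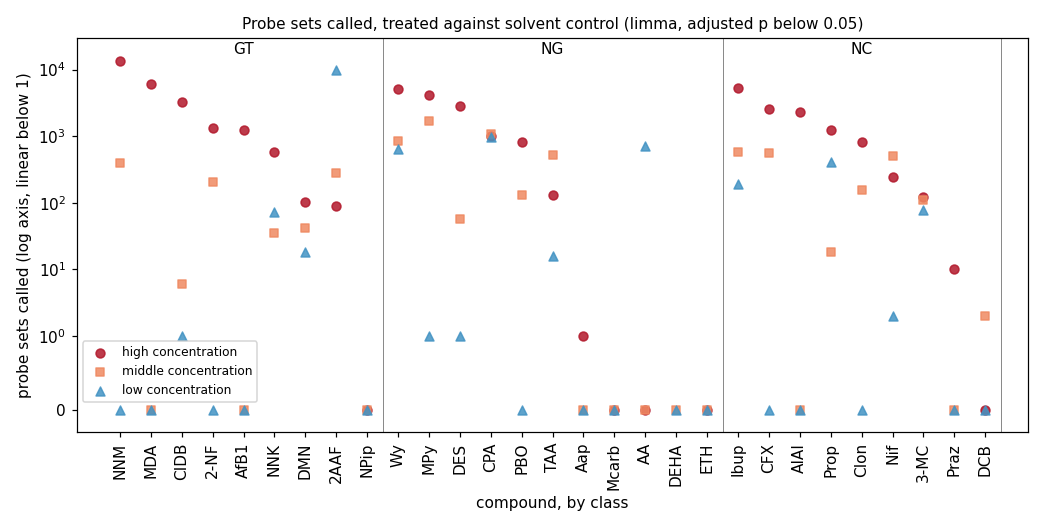
Number of probe sets called per compound at its high, middle and low concentration (logarithmic axis, linear below 1), grouped by class. NNM had the most calls at its high level (13297), and 2AAF was the compound with the most at the low level (9861).

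**Figure D2:**
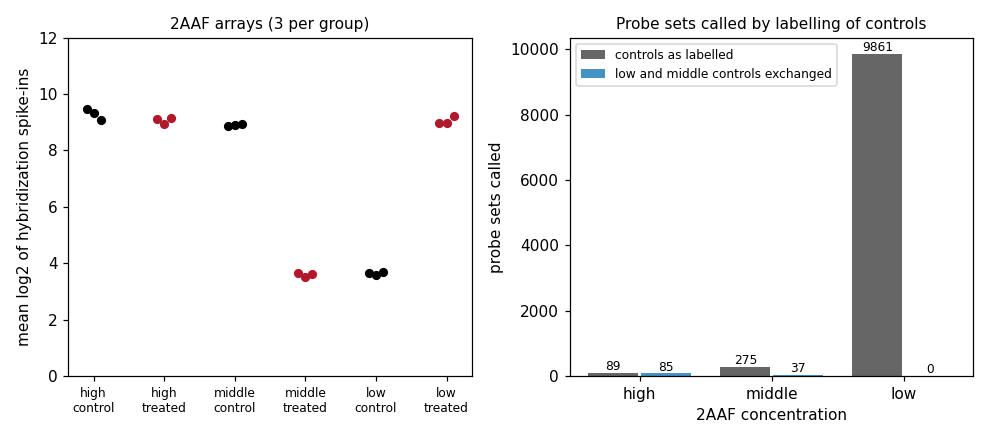
Mean log2 signal of the hybridization spike-ins on each 2AAF array, and the number of probe sets called at each concentration with arrays as labelled and with the low and middle controls exchanged. As labelled the counts were 89, 275 and 9861 at the high, middle and low level, and after the exchange 85, 37 and 0.

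Among the largest single responses at the highest concentration were rises of probe sets, some with low values in control cells. Others had higher values, such as 1370269_at with a control mean of 9.18 for piperonylbutoxide. For ibuprofen at 920 µM, 1398250_at rose from 3.71 ± 0.04 (SD) to 9.57 ± 0.35, a log2 fold change of 5.86 ± 0.35 (SE, adjusted p 9.00e-06). Piperonylbutoxide at 31.69 µM raised the same probe set by 5.07 ± 0.16 (adjusted p 1.09e-08) and 1370269_at by 4.50. For 3-methylcholanthrene at 5.76 µM, with 2 dishes, 1368990_at rose by 5.46 ± 0.25 (adjusted p 3.35e-06) and 1370269_at by 4.76. Wy-14643 at 540.43 µM raised 1370902_at by 3.41 ± 0.16 (adjusted p 9.66e-08). It lowered 1370019_at from 11.79 ± 0.25 to 6.54 ± 0.16, a log2 fold change of -5.25 ± 0.10 (adjusted p 1.39e-10). C.I. Direct Black at 17.28 µM raised 1390458_at by 3.67 ± 0.18 (adjusted p 4.17e-08). With methapyrilene at 44.39 µM the log2 fold change of 1385016_at was -3.91 ± 0.15 (adjusted p 6.34e-08).

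The probe set 1398250_at responded to Wy-14643 mainly below the highest concentration, a case singled out after its values were seen. Its log2 fold change was 9.23 ± 0.51 (SE, adjusted p 3.57e-06) at 60.05 µM, 7.65 ± 0.51 (adjusted p 1.38e-05) at 180.14 µM and 0.75 ± 0.51 (adjusted p 0.376) at 540.43 µM. The difference between the low and the high concentration was 8.48 ± 0.72 (adjusted p 2.33e-05). Treated values were 12.55 ± 0.17 (SD) at the low and 5.70 ± 0.62 at the high concentration. Of the control arrays of the high concentration, replicate 1 was at 8.10 and the lowest at 3.35, and without replicate 1 the log2 fold change at that concentration was 1.96. For ibuprofen it was 7.60 at 102 µM and 5.64 at 306.67 µM, and the difference between its low and high concentration, 1.74 ± 0.50, had an adjusted p of 0.0788. The control means of ibuprofen were 4.34 at 102 µM and 5.84 at 306.67 µM, and the treated means 11.93 and 11.48. For piperonylbutoxide the order was the opposite, with 0.18 at 3.52 µM and 3.81 at 10.56 µM, and a difference between low and high of -4.90 ± 0.23 (adjusted p 1.02e-06). Some other probe sets followed the labelled order of Wy-14643 concentrations, but 1370019_at was named for its large fall at the high concentration, which favours this order. From low to high the log2 fold change was -1.13, -3.55 and -5.25 for 1370019_at and -1.84, -2.47 and -3.57 for 1367631_at. For 1370080_at it was -0.86, -0.77 and 0.56. Across probe sets, the effects of Wy-14643 at the high and low level correlated at 0.0608. High and middle effects correlated at 0.571, and middle and low effects at 0.442. Whether arrays were exchanged between these concentrations was not tested.

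NNM and MDA had the most calls, and each of these counts fell when a technical term was fitted. For NNM at 152.33 µM, 2 of the 3 control arrays and no treated array were in the batch of lower medians. No other group of NNM arrays mixed the batches, so the batch term rests on these 3 control arrays. With the term, the treated arrays are in effect compared with the only control array outside that batch. A lower count with the term can therefore come from less power. The count was 1883 with the batch as a term and 8697 after quantile normalization. The probe set 1370157_at rose by 1.75 ± 0.10 (SE, adjusted p 3.84e-06), and by 1.90 ± 0.23 with the batch term (adjusted p 0.000243). For 1369679_a_at the values were -2.74 ± 0.26 (adjusted p 5.19e-05) and -2.67 ± 0.41 (adjusted p 0.00124). For MDA at 9.81 µM, 2 of the 3 treated arrays and no control array lacked spike-in signal. The count was 1577 with the spike-in signal as a term. The probe set 1382882_x_at rose by 3.55 ± 0.37 (adjusted p 0.000133), and by 4.21 ± 0.43 with the term (adjusted p 3.88e-05). For 1395840_at the log2 fold change was -3.14 ± 0.47 (adjusted p 0.00105), -2.78 and no longer called without replicate 1, and -2.76 ± 0.83 with the term (adjusted p 0.0664). With both terms the total over all compounds was 36801.

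The counts of the 6 compounds with most calls changed when a replicate was left out. Each such fit has fewer dishes and less power, so a lower count need not mean dependence on 1 replicate. For NNM the count was 7444 without replicate 1 and 4353 without replicate 2. For MDA it was 388 without replicate 1, 13806 without replicate 2 and 1001 without replicate 3. For ibuprofen these counts were 1829, 2825 and 2168. For Wy-14643 it was 2031 without replicate 2 and 2697 without replicate 3. For methapyrilene it was 2330 without replicate 1 and 1333 without replicate 2, and for C.I. Direct Black 800 without replicate 2. With no replicate block the counts were 14363 for NNM, 7069 for MDA, 5730 for ibuprofen, 5013 for Wy-14643, 4425 for methapyrilene and 4036 for C.I. Direct Black.

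The split between rises and falls moved with scaling for several compounds. Quantile normalization changed the share of rises from 31.5% to 42.9% for methapyrilene, from 68.3% to 57.3% for C.I. Direct Black, from 57.8% to 37.4% for dimethylnitrosamine and from 8.96% to 19.5% for aflatoxin B1. For nifedipine it changed from 84.2% to 68.3%, for NNK from 55.6% to 40.8%, for allyl alcohol from 19.9% to 33.6% and for 3-methylcholanthrene from 57.9% to 45.3%. The median log2 fold change over all probe sets was 0.13 for MDA and 0.14 for acetaminophen at the high level and -0.12 for 2AAF at the low level, and 0.07, 0.04 and -0.08 after quantile normalization. Of the control genes, tested in 29 compounds, GAPDH fell with Wy-14643 (-0.94, adjusted p 0.00247) and with ibuprofen (-0.70, adjusted p 0.0180). Beta-actin fell with Wy-14643 (-0.68, adjusted p 0.0103). After quantile normalization these values were -0.85, -0.67 and -0.59. Hexokinase was called in 0 of the 29 by limma, with an unadjusted p under 0.05 in 2 of them, and the p-values were adjusted over the 87 tests.

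The third comparison asked whether compounds shared responding probe sets. Unrelated compounds changed many of the same probe sets, and the shared changes were mostly falls. In total, 2000 probe sets were called in one direction in at least 5 compounds, 1573 falling and 427 rising. Random reassignment of each compound's calls over the tested probe sets gave 47.1 on average and at most 68 in 1000 draws (one-sided permutation p 0.001, the smallest possible). The reassignment takes all probe sets as independent and equally likely to be called. It therefore cannot tell shared responses from probe sets that are called more readily or change together. The probe set 1385016_at fell in 18 compounds, with a mean log2 fold change of -1.85, and 1377375_at in 17 (-1.71), while it rose in 1. The probe set 1387599_a_at rose in 14 compounds (mean 0.998), and 1384427_at in 13 (0.85), while it fell in 1. With no replicate block the count was 2231. It was 827, 494 and 985 without replicates 1, 2 and 3, and 1512 with the terms for NNM and MDA given above. After quantile normalization it was 1897. The main axis of the effects over 85 comparisons followed the differences between treated and control arrays in array median (r = 0.727), in the 95% quantile (r = -0.748) and in GAPDH 3' minus 5' signal (r = 0.452).

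The fourth comparison asked whether genotoxic compounds, non-genotoxic carcinogens and non-carcinogens differed in their effects. The classes differed little as groups, and the clearest difference was a single probe set higher with genotoxic than with non-genotoxic compounds. With each compound as 1 value, limma called 0 probe sets between GT and NC compounds and 0 between NG and NC compounds. The unadjusted counts were 785 and 1302, against 1552.1 by chance. Between GT and NG compounds 1 was called, with an unadjusted count of 477. This was 1379365_at, with a mean log2 fold change of 0.94 ± 0.61 (SD, n = 9) in GT and -0.33 ± 0.45 (n = 11) in NG compounds. The difference was 1.27 ± 0.21 (SE, adjusted p 0.0364). Its mean was above 0 in 9 of 9 GT, 2 of 11 NG and 8 of 9 NC compounds. The fit with no replicate block gave the same counts of 0, 0 and 1.

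This call was not stable. It was lost (count 0) at the middle concentration, with the mean over all concentrations, with effects scaled to equal size, with trend and robust settings and with the array batch as a term. It was also lost without the 4 distant arrays, without NNM and MDA, and within the batch of higher medians. Each compound was assigned to the batch of most of its arrays at the highest level, which placed all 9 GT and 11 NG compounds but only 3 NC compounds in the batch of higher medians. Some arrays of these compounds were in the other batch, 2 controls of NNM and 1 treated array of ethionine, so neither fit removes the batch from the effects of NNM and ethionine. The difference was again 1.27 with the batch term (SE 0.21, adjusted p 0.0552) and within the batch of higher medians (SE 0.22, adjusted p 0.134). It could not change, because no GT or NG compound was assigned to the other batch, so these fits do not test whether it depends on batch. The call ended because the unadjusted p rose from 1.17e-06 to 1.78e-06 and 4.30e-06, with a slightly larger SE and fewer degrees of freedom. Over the 12 alternatives the adjusted p ranged from 0.0145 to 0.999958, and 4 kept the call. The interval of the difference lay within 2-fold for 99.2% of probe sets between GT and NC, 98.9% between NG and NC and 99.3% between GT and NG, with median half-widths of 0.22, 0.21 and 0.21 on the log2 scale. The numbers of calls per compound did not differ detectably between classes. Their medians were 1250 for GT, 130 for NG and 830 for NC compounds (permutation test of ranks, two-sided p 0.473). These medians and their order were not stable. They were 757, 834 and 548 with no replicate block, 388, 25 and 173 without replicate 1, 110, 12 and 7 without replicate 2 and 1001, 159 and 356 without replicate 3. Without the 4 distant arrays they were 1250, 829 and 830. The compounds at the medians changed as well, aflatoxin B1 from 1250 to 7 without replicate 1 and 10 without replicate 2, and clonidine from 830 to 173, 1 and 198 without replicates 1, 2 and 3. Effects correlated within classes (mean 0.0785) about as much as between them (0.0775, one-sided permutation p 0.402).

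Within single compounds, rises of 2 probe sets were called most often in GT compounds, and also in some NC compounds. The probe set 1379365_at rose in 6 of 9 GT and 2 of 9 NC compounds, and fell in 2 of 11 NG compounds, of which none had a called rise. The probe set 1370157_at, chosen after its values were seen, rose in 6 GT, 1 NG and 3 NC compounds. Its log2 fold change was 2.99 ± 0.13 (SE) for 2AAF at 0.99 µM, 2.74 ± 0.22 for aflatoxin B1, 2.73 ± 0.15 for 2-nitrofluorene, 2.38 ± 0.15 for NNK and 1.93 ± 0.21 for dimethylnitrosamine. It also rose by 2.72 ± 0.25 with 3-methylcholanthrene (2 dishes) and by 2.02 ± 0.16 with allyl alcohol, both in the NC class of the submitters' table. The difference between GT and NG compounds was 1.63 ± 0.37 and was not called (adjusted p 0.99997).

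**Figure D3:**
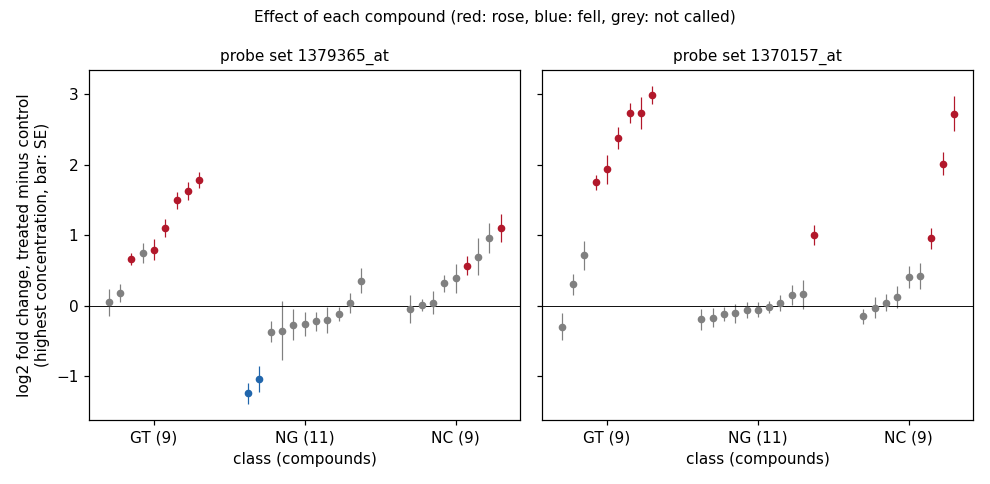
Log2 fold change ± SE of 1379365_at and 1370157_at at the highest concentration of each compound, grouped by class, with called rises in red, called falls in blue and others in grey. Both probe sets were called as rises in 6 of the 9 GT compounds, and in 0 and 1 of the 11 NG compounds.

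The fifth comparison asked whether related compounds at equal concentrations differed. Between dimethylnitrosamine, NNK and N-nitrosopiperidine, all N-nitrosamines, few differences were called, and for acetamide and methylcarbamate none was called with all dishes. Few calls do not show alike effects, as simulated differences of 0.5 were recovered in only 8.96%. Effects correlated across probe sets, which are not independent replicates, at -0.437 for NNK and N-nitrosopiperidine and -0.147 for dimethylnitrosamine and NNK at 333 µM. The other correlations among these N-nitrosamines lay between 0.163 and 0.474. Their unadjusted counts ranged from 1647 to 3941, where chance gives 1552.1. In total, 18 differences were called. Dimethylnitrosamine and NNK differed in 9 probe sets at 1000 µM and 3 at 333 µM, dimethylnitrosamine and N-nitrosopiperidine in 1 and 1, and NNK and N-nitrosopiperidine in 0 and 4. The unadjusted count for that 0 was 2790, and without replicate 1 it became 1299 calls. For acetamide and methylcarbamate limma called 0 at 1000, 333.3 and 111.1 µM, with unadjusted counts of 2013, 3155 and 1618. Without replicate 1 the calls were 5, 0 and 48. The probe set 1379365_at rose with dimethylnitrosamine at 333 µM (2.31) but not with NNK (0.23), a difference of 2.08 ± 0.18 (adjusted p 1.73e-06). At 1000 µM it rose with both, by 1.63 and 1.498, and no difference was called. At 333 µM the difference of dimethylnitrosamine from N-nitrosopiperidine (0.10) was 2.21 ± 0.24 (adjusted p 0.00139). At 1000 µM 1371076_at changed by -0.98 with dimethylnitrosamine and by 0.85 with NNK, a difference of -1.83 ± 0.19 (adjusted p 6.76e-05). At 333 µM 1368519_at changed by 1.28 with NNK and -1.50 with N-nitrosopiperidine, a difference of 2.79 ± 0.28 (adjusted p 0.000433).

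With no replicate block the total was again 18, but single comparisons changed. Dimethylnitrosamine and NNK then differed in 5 probe sets at 1000 µM and 6 at 333 µM, dimethylnitrosamine and N-nitrosopiperidine in 2 and 3, and NNK and N-nitrosopiperidine in 2 and 0, so the 4 calls at 333 µM were lost. The total was 1797 without replicate 1, 4 without replicate 2 and 5 without replicate 3. The call for dimethylnitrosamine and N-nitrosopiperidine at 1000 µM was lost (0) without the 4 distant arrays, 1 of which was a control of N-nitrosopiperidine. Between 84.5% and 97.4% of the intervals lay within 2-fold. Other related pairs were used at unequal concentrations and are set side by side untested. 2-nitrofluorene had 1342 calls at 43.13 µM (286 without replicate 1, 501 without replicate 2), and 2AAF had 89 at 0.99 µM (3 without replicate 1, 1 without replicate 3, 173 with no replicate block). Acetamide had 0 at 1000 µM, and thioacetamide had 130 at 78.67 µM (18 without replicate 1, 12 without replicate 2, 31 with no replicate block). N-nitrosopiperidine had 0 at 1000 µM (1653 without replicate 1), and NNM 13297 at 152.33 µM (7444 without replicate 1, 4353 without replicate 2).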

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

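In this part the tests on the acetaminophen array, the spike-in comparison for 2AAF, the exchange of its controls and the counts without distant arrays were chosen after the data were seen.

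Among related compounds, the effects of dimethylnitrosamine and NNK differed in 9 probe sets at 1000 µM and in 3 at 333 µM. The 3 were 1379365_at, 1370157_at and 1371076_at. Dimethylnitrosamine and N-nitrosopiperidine differed in 1 at 1000 µM (1371076_at) and 1 at 333 µM (1379365_at). NNK and N-nitrosopiperidine differed in 4 at 333 µM, 1368519_at, 1368174_at, 1392264_s_at and 1392835_at. Each difference was tested directly. Leaving out 1 replicate gave between 0 and 14 for the first pair at 1000 µM and 3 each time at 333 µM, between 0 and 49 and between 0 and 1 for the next pair, and between 0 and 378 for the last. The 4 calls of the last pair became 0 with no replicate block. For NNK and N-nitrosopiperidine at 1000 µM the count was 0, and 1299 without replicate 1. Of 100 random regroupings of the dishes, the real one included, 6 gave at least the total of 18, and the highest of the others was 22, so chance is not excluded for this total.

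Between GT and NG compounds 1 probe set was called, 1379365_at. Of 100 random splits of the compounds, the real one included, 2 called as many, and the other of these called 2. This share lies under 0.05 for this comparison alone. It is not adjusted for the other class comparisons, and the call depended on the processing, so chance is not excluded. Between GT and NC and between NG and NC compounds, where the count was 0, all 100 splits called at least as many, and the highest other was 0. These splits exclude nothing.

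For 2 compounds the low concentration had more calls than the high one, and the effects at these concentrations differed. For acetamide there were 712 calls at the low and 0 at the high level, and the difference was called for 267 probe sets. The count of 712 was 182 without replicate 2, 12 without replicate 3, 0 with a spread pooled over all compounds, 403 with trend and robust settings and 1210 with no replicate block. No explanation was tested for acetamide. For 2AAF there were 9861 calls at the low and 89 at the high level, and the difference was called for 4662 probe sets.

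The hybridization spike-ins of 2AAF, which no comparison of the report uses, differed between treated and control arrays by 5.404 on the log2 scale at the low and by -5.31 at the middle level, ranks 2 and 1 of 86 when set against the spread between replicates. A single effect graded over the concentrations is argued against by the correlation of low and high effects across probe sets, -0.14. Technical explanations stay open: arrays from different batches, in line with the rank of 2, an exchange of the low and middle controls, after which 0 probe sets were called at the low level, 37 at the middle and 85 at the high level, or a shift shared by arrays without spike-in signal. That shift, measured within groups of other compounds, correlated with the low effect at -0.76, with a slope of -1.03. With the middle effect, where the treated arrays lacked the signal, it correlated at 0.48. The middle effect was smaller, with 275 calls against 9861 at the low level. Its median absolute log2 fold change was 0.105, against 0.227 at the low level. Against the exchange counts that the correlation of high and middle effects went from 0.325 as labelled to 0.0274. That of high and low effects went from -0.14 as labelled to -0.00446, which does not count against the exchange. No test separates these explanations, since the low controls and the middle treated arrays were the 6 of 2AAF without spike-in signal.

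On the high treated replicate 1 of acetaminophen the hybridization spike-ins had a mean of 13.68, above every other array (at most 11.81). Another treatment of the same cells under a wrong label is argued against by its highest correlation with any other array, 0.360. An effect of acetaminophen alike on all dishes is argued against by replicates 2 and 3, whose lower median correlation with other arrays was 0.961. Little hepatocyte RNA on this array stays open and is in line with the spike-ins of 13.68, beta-actin at 6.85 (others at least 8.23) and GAPDH at 6.22 (others at least 6.43), whether from handling or from loss of cells in that well. Without this array 947 probe sets were called at the high level, 197 rising and 750 falling, and 21 at the middle level.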

How the results depend on the processing

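In this part the terms for array batch and spike-in signal, the fits within batches, and the settings without 2AAF, without NNM and MDA, without the 4 distant arrays and with exchanged controls were chosen after the data were seen.

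Counts given here as moved changed by more than 1.5 times, and the cause was not tested unless stated. With 1 spread pooled over all compounds, the middle level total moved from 7227 to 17491, NNM from 13297 to 7754, C.I. Direct Black from 3282 to 1248, Wy-14643 from 5068 to 3279, MDA from 6119 to 9402, ibuprofen from 5317 to 9537 and the total between related compounds from 18 to 58. With trend and robust settings the middle level total was 3946 and the related compounds total 8. Quantile normalization moved NNM to 8697. With probe sets brighter than the median only, the count was 7687 for NNM and 8903 for T0 against control, where fewer probe sets were tested. A 2-fold minimum left 544 for T0, by its construction. Without 2AAF the low level total was 3117, because 9861 of its calls came from that compound.

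The call between GT and NG compounds was lost (0) at the middle concentration, with the mean over all concentrations, with eBayes trend and robust settings, with compounds scaled to the same root mean square effect, with the array batch as a term, with compounds of the high-median array batch only, without the 4 arrays far from the rest and with NNM and MDA left out. The counts of 0 between GT and NC and between NG and NC compounds stayed 0 in every setting run.

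Leaving out each replicate in turn leaves fewer dishes. The ranges were 28812 to 36915 for the highest level total, 1518 to 10895 for the middle, 5947 to 10454 for the low and 494 to 985 for shared responses. They were 4353 to 11243 for NNM, 388 to 13806 for MDA, 1829 to 2825 for ibuprofen, 2031 to 4592 for Wy-14643, 1333 to 3683 for methapyrilene, 800 to 3210 for C.I. Direct Black and 4 to 1797 between related compounds. Where 1 dish remained, its values were assumed to vary like those of the other groups.

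With the array batch as a term and no replicate block, NNM had 1883 calls, and with the spike-in signal as a term MDA had 1577. Each of these terms coincides in part with treatment in that compound, so it can also remove part of any effect. For NNM the treated arrays are then in effect compared with the only control array outside the batch of lower medians, which lowers power. With no replicate block and no such term, the totals per level, the shared, class and related compound counts and the counts of the 6 compounds with most calls stayed within 1.5 times. Counts of other compounds moved at the highest level, such as acetaminophen from 1 to 834, thioacetamide from 130 to 31, propranolol from 1258 to 548 and dimethylnitrosamine from 102 to 236. The total between related compounds stayed at 18 although its single comparisons changed.

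Of the 86 counts per compound and level, 34 moved with no replicate block, 58 with the pooled spread, 8 with brighter probe sets, 9 after quantile normalization, 38 with trend and robust settings, and 51, 54 and 46 without replicates 1, 2 and 3. Of 42 log2 fold changes of named probe sets in compounds, 41 kept their call with no replicate block, 39 with the pooled spread, 41 after quantile normalization, and 39, 36 and 38 without replicates 1, 2 and 3, and 0 reversed. The 4 for T0 kept theirs in both alternatives run. The 42 were chosen as the largest changes among probe sets called and changed in the same direction in every dish. Leaving out a replicate therefore could not reverse them, and the choice also favours keeping the call.

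Testing all probe sets of a gene was not run, because every probe set was already tested by itself. The gene lists and their alternatives were not run, because the files used here do not pair probe sets with genes. Detection calls were not used here, so whether a probe set of low value lay above background was not tested.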

Other observations

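In this part the tests of the splits and of the axis below were chosen before their results were seen, while the batch limits, the arrays listed and the overlaps between levels were chosen after.

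Effects of unrelated compounds lay along 1 axis with either sign, a first component with 26.3% of the variance of 85 comparisons, without acetaminophen at the high level. Differences between array distributions are argued against as its whole source, because 24.5% remained after quantile normalization, a ratio of 0.931, although the score followed the difference in array median (r = 0.727). RNA integrity stays open, since the score correlated with the difference in GAPDH 3' minus 5' signal at r = 0.452 (two-sided permutation p 1e-05, the smallest possible, adjusted over 5 relations 1.67e-05), between the bounds of 0.3 and 0.5 set in advance. Other measures fell on both sides: rank correlation 0.557, 0.545 without the 2 farthest comparisons, 0.645 and 0.448 within the batches of lower and higher medians, and 0.182 for beta-actin 3' minus 5' (p 0.0959, adjusted p 0.0959). The permutations take the 85 comparisons as independent, but levels of a compound can be related. Effects at the high and middle level of MDA correlated at 0.720, those at the middle and low level of N-nitrosopiperidine at -0.594. The permutation p-values of this paragraph may therefore be too small. A compound effect that grows with concentration stays open too, as the absolute score was larger at the high than at the low level in 17 of 27 compounds (exact two-sided sign test p 0.248). The spike-in signal stays open as well. With its difference the score correlated at r = -0.309 (two-sided permutation p 0.0057, adjusted p 0.0071), but at 0.628 and -0.492 within the batches of lower and higher medians. The rank correlation was 0.216, and r was -0.128 without the 2 farthest comparisons. The lowest score (-0.383, 2AAF low level) and the highest (0.380, MDA high level) came from comparisons where only control or only treated arrays lacked that signal.

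Random regroupings of the arrays of each compound were fitted with no replicate block, 100 in all with the real one included. The real grouping alone reached its own value, 1 of 100 each time, so a random grouping of the arrays within compounds is excluded at a share of 0.05. The real total was 58261 at the highest level (highest other 19603), 8525 at the middle (1910) and 14301 at the low level (11802). The number of compounds with at least 20 calls was 22 (highest other 6), and 2231 probe sets were shared by at least 5 compounds (highest other 1). Regrouping left few compounds with calls to share, so this last value does not test sharing itself. Of the 14301 calls at the low level, 11188 came from 2AAF, whose control arrays there lacked spike-in signal while the treated arrays had it. For the low level the regroupings therefore cannot tell treatment from that difference. At the highest level NNM gave 14363 of the calls and MDA 7069. In these compounds the array batch or the spike-in signal also differed in part between treated and control arrays. The regroupings cannot tell treatment from these differences either.

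For T0 against solvent control 2 of 100 splits reached 13914, the real one included, and the highest other called 14376. That split followed the array batch: 47.1% of its smaller group and 20.7% of its larger group were in the batch of lower medians. When splits were drawn within batches, the real one called 17041 (highest other 680) in the batch of higher medians and 13456 (highest other 1) in the other. Chance is thus excluded at a share of 0.05 for this comparison, if the control values of different compounds are independent.

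For the 27 compounds with 3 treated and 3 control arrays at the highest level there are only 10 splits each, too few for a share under 0.05. Real value and highest other were 1659 and 1 for 2-nitrofluorene, 236 and 1510 for dimethylnitrosamine, 757 and 102 for aflatoxin B1, 14363 and 0 for NNM, 4036 and 7 for C.I. Direct Black, 4425 and 0 for methapyrilene, 31 and 214 for thioacetamide, 2348 and 0 for diethylstilbestrol and 5013 and 0 for Wy-14643. They were 1506 and 1 for piperonylbutoxide, 3331 and 1 for cefuroxime, 406 and 0 for nifedipine, 548 and 0 for propranolol, 349 and 0 for NNK, 173 and 21 for 2AAF, 7069 and 0 for MDA, 2 and 0 for acetamide and 1 and 0 for dehydroepiandrosterone. For acetaminophen they were 834 and 0, for cyproterone acetate 997 and 0, for clonidine 1509 and 1, for ibuprofen 5730 and 0, for allyl alcohol 2751 and 0 and for methylcarbamate 0 and 330. For N-nitrosopiperidine, ethionine and 1,4-dichlorobenzene both were 0. The real split was the highest in 21 of the 27, was exceeded by 1 other in dimethylnitrosamine and in thioacetamide (2 of 10 splits reached the real value), and was reached by all 10 in the 4 compounds with a real value of 0. The splits with 1510 and 214 calls, several times the real counts, and that with 330 calls, where the real count was 0, point to a structure of these arrays other than treatment. For dimethylnitrosamine that split put control replicates 1 and 2 with treated replicate 1.

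Other values of the arrays were as follows. Spike-in signal was absent from 3 low control and 3 middle treated arrays of 2AAF, from 3 control and 2 treated arrays of methylcarbamate at the high level, and from 2 high and 1 low treated arrays of MDA. It was also absent from 1 high and 1 low control array of N-nitrosopiperidine. The 4 distant arrays had median correlations of 0.307 (acetaminophen high treated replicate 1), 0.841 (dehydroepiandrosterone middle control replicate 1), 0.8999 (N-nitrosopiperidine high control replicate 2) and 0.902 (T0 replicate 19). Among control means wholly in 1 array batch, 18 in the lower and 59 in the higher, 28325 probe sets were called between the batches. With the batch as a term and no replicate block, NNM had 870 calls at the middle level and ethionine 3 at the high level, where the fit with neither had 850 and 0.

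Probe sets called at both the high and the low level of Wy-14643 were 205 in the same and 183 in opposite directions, where 52.9 in the same direction are given by independence. At the high and middle levels those called in the same direction were 147 for 2-nitrofluorene (4.42 by independence), 393 for cefuroxime (21.8) and 112 for nifedipine (1.77).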
